A study of Schmidtea mediterranea with 8 samples.

How the data were processed

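Total RNA from the planarian Schmidtea mediterranea was profiled on 8 single-colour NimbleGen arrays in 4 groups of 2: nanos(RNAi) and control(RNAi) animals of an asexual strain, and the same treatments in juveniles of a sexual strain. Per the labels, the replicates of a group were biological replicates from separate RNAi feedings. The culture medium, Montjuic salts, was used at 1 X and 21°C for asexual animals and at 0.75 X and 18°C for juvenile sexual animals, per the labels' protocols. RNA was purified with a column kit and DNase and labelled with Cy3 by the array maker, per the labels' protocols. The arrays hold 60-mer probes for 16797 expressed sequence tags (ESTs), each EST with a median of 10 probes in 2 on-array copies, and 57333 or 57553 random control probes per array.

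The probe tables hold scanner intensity per probe, deposited without background correction or normalization and written by NimbleScan 2.3.78, 2.4.27 or 2.4.31, per the file headers. Their mismatch column is 0 for every probe. The RMA tables hold 1 linear intensity per EST and on-array copy, deposited after RMA, per the submitters' processing notes, which give no version or settings. In the value table of the series each column equals the mean of both copies in a single sample's RMA values, so its scale is linear intensity without centring, and a single-colour value has no ratio direction. None of scale, centring and direction stays unknown. Which arrays the authors normalized together is not given in the sources used here. The column medians of the value table were 3400 and 3386 for asexual nanos and control replicate 1, 3235 and 3222 for asexual nanos and control replicate 2, 554 and 550.1 for juvenile sexual nanos and control replicate 1, and 554 and 551 for juvenile sexual nanos and control replicate 2.

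The deposited records differ on 2 arrays. In 6 of the 8 columns, 100% of ESTs equalled the RMA values of the same sample within 0.01 intensity units. The columns of juvenile sexual control replicate 1 and juvenile sexual nanos(RNAi) replicate 2 each equalled the RMA values of the other sample for 100% of ESTs, and their own for 0.0357%. Every result was therefore computed with the arrays grouped as the per-sample tables are attached ("sample-file grouping", the design as planned) and as the value table places them ("value-table grouping", added after the difference was seen), and both are given with equal standing. Both records place juvenile sexual nanos(RNAi) replicate 1 and control replicate 2 alike.

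The file headers divide the arrays into 3 array sets, with asexual replicate 1 (nanos and control) in set 1, asexual replicate 2 in set 2 and all 4 juvenile sexual arrays in set 3. Strain and array set are therefore confounded, and for the asexual arrays the replicate number is also the array set. The array design of set 1 lacks 11 ESTs named Smed_, among them nanos, which leaves 1 array per asexual group for these ESTs.

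Probe intensities were background-corrected with normexp (limma 3.58.1, offset 50, fitted with the random probes included), quantile-normalized over the 8 arrays, taken to log2 and averaged over the 2 copies, and probes of an EST were combined by median polish. An EST counted as above background on an array where its median raw intensity exceeded the 95th percentile of the random probes of that array. ESTs above background on at least 2 arrays were tested, which kept 15789 and left out 1008. The arithmetic used R 4.3.3 with the data.table package, version 1.17.8, and plots used python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The number of arrays limits the precision of every value.

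Differences were tested with limma (lmFit and eBayes) on 1 model with a mean for each of the 4 groups, so that all arrays share the estimate of spread. Tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p under 0.05. The comparisons were nanos(RNAi) minus control in asexual animals, the same in juvenile sexual animals, the mean of these effects, their difference, and juvenile sexual control minus asexual control. ESTs called lower in both strains were counted and compared with unrelated lists by Fisher's exact test over ESTs, which are not independent replicates. The fold of a single EST between 2 groups of which 1 lay below background on every array is printed as a bound, and its fitted log2 value is no exact size: the mean log2 value of the bright group against the dim group's mean of, per array, the higher of the EST's own value and the lowest value among ESTs above background on that array. No such bound was made for the mean effect or the strain difference in the effect. The lowest value above background can lie under the level at which other ESTs were still below background. On juvenile sexual control replicate 2 it was 8.19, while nanos lay below background at 8.98. Folds printed as "at least" can therefore overstate the least fold.

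Design, comparisons, thresholds and the rule for naming ESTs were fixed before the data were examined. The rule names, per comparison and direction, up to 15 ESTs that carry a gene name in the files, lie past the threshold and move the same way in every pair of arrays; where under 5 pass, the 5 with the smallest p are named with their values. It adds every EST named nanos. Of ESTs without a gene name, at most 2 that rose and 2 that fell are printed per comparison, those with the largest fold past the threshold. The files give gene names for 12 ESTs only, and the sources used here pair no other EST with a gene. Of 13 gene lists planned for a camera test (germ cells, meiosis, testis, female organs, neoblasts, cell cycle and other cell types), 0 reached the 5 members needed, so no list was tested; the germ cell list had 1 member (nanos), the nervous system list 1, and the other lists 0.

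Counts were recomputed, where the setting applies to the comparison, without background correction, with 75th percentile scaling, with quantile normalization within each strain, with the mean of probes, with each on-array copy alone, from the authors' RMA values with and without a further quantile step, from the value table, with no filter or a filter on all 8 arrays, with intensity trend and robust moderation, from the 4 arrays of a single comparison alone (each strain's effect and the strain comparison), with a replicate or array-set block, and without each array in turn. The strain comparison was not run with quantile normalization within each strain, on the authors' RMA values without a further quantile step or on the value table. Subtraction of mismatch probes could not be run because the mismatch column is 0. All divisions of the 8 arrays into 4 and 4 were fitted for the mean effect, except the division by strain, for which the model could not be fitted.

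The pipeline's model step was tested on simulated values built from the arrays' own means and spread, with 15778 ESTs and 100 ESTs changed per fold size in each comparison. For the asexual effect it called 60% of ESTs changed 2-fold and 96% of those changed 4-fold with the sample-file grouping, and 62% and 97% with the value-table grouping. For the juvenile sexual effect the shares were 70% and 93%, and 64% and 97%. For the mean effect they were 82% and 99%, and 90% and 99%; for the strain difference in the effect 19% and 67%, and 30% and 75%; for the strain comparison of controls 56% and 95%, and 61% and 98%. False calls numbered 5 to 12 per comparison. These shares are averages over ESTs picked at random, with deviations drawn independently between arrays, which the real arrays need not follow. An EST with a large spread can be missed. Contig6300_SE3 had an asexual log2 difference of −2.84 with the sample-file grouping, yet an SE of 1.84 and an adjusted p of 0.931 by limma. A count of 0 calls therefore does not exclude 4-fold changes.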

Results

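Transcript levels of 16797 ESTs were measured in nanos(RNAi) and control(RNAi) planarians of an asexual strain and in juveniles of a sexual strain, with 2 arrays in each of the 4 groups. The labels describe nanos(RNAi) animals as germ cell-less. Median raw probe intensity was 2826 to 3706 on the 4 asexual arrays, where 91.8% to 92.5% of ESTs lay above background, and 762 to 859 on the 4 juvenile sexual arrays, where 77.6% to 82.1% did. At most 37 spots on an asexual array and 265 on a juvenile sexual array were saturated. Across ESTs, which are not independent replicates, the replicates correlated at r = 0.993 for asexual nanos(RNAi) (SD of the difference 0.22 log2) and 0.980 for asexual control (SD 0.37).

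The juvenile sexual arrays fell into pairs of close arrays, which the records group differently. The array filed as control replicate 1 was closest to the array labelled nanos(RNAi) replicate 1 (r = 0.993, SD of the difference 0.22 log2), and the array filed as nanos(RNAi) replicate 2 was closest to control replicate 2 (r = 0.987, SD 0.30). The sample-file grouping puts r = 0.962 (SD 0.52) within the nanos(RNAi) group and 0.974 (SD 0.43) within the control group. The value-table grouping exchanges these 2 arrays and puts the closest arrays together. As filed, each close pair is a nanos(RNAi) and a control array of the same replicate number. Closeness alone therefore does not tell an exchange of arrays from a difference between the replicates. The value-table grouping then compares what the sample files call replicate 1 with replicate 2.

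The nanos transcript itself was measured first, since it is the target of the RNAi. In asexual animals it fell from 9.50 in control to 6.99 in nanos(RNAi) on the replicate 2 arrays, a log2 difference of −2.51 and at least 5.39-fold, with the nanos(RNAi) value below background; the replicate 1 arrays do not carry this EST. limma gave it an adjusted p of 0.93 with the sample-file grouping and 0.0637 with the value-table grouping, neither past the threshold. On the juvenile sexual arrays nanos was 9.18 on the array labelled nanos(RNAi) replicate 1, 9.50 on the one filed as control replicate 1, 8.98 on the one filed as nanos(RNAi) replicate 2 and 8.98 on control replicate 2. Its raw probes there lay at 1.10, 1.18, 1.01 and 0.927 times the background level, against 4.29 times in asexual control, so nanos does not check the labels of the juvenile sexual arrays. The log2 difference was −0.16 with the sample-file grouping (adjusted p 1) and 0.36 with the value-table grouping (adjusted p 0.679), neither past the threshold. In asexual animals Smed_nanos passed the threshold under 75th percentile scaling (log2 −3.29, adjusted p 0.045 and 0.00317 with the 2 groupings) and in the authors' value table (−4.99, adjusted p 0.0194), and, with the value-table grouping, under quantile normalization within each strain (−3.14, adjusted p 0.00301) and with the array set as a block (−2.51, adjusted p 0.0228).

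**Figure D1:**
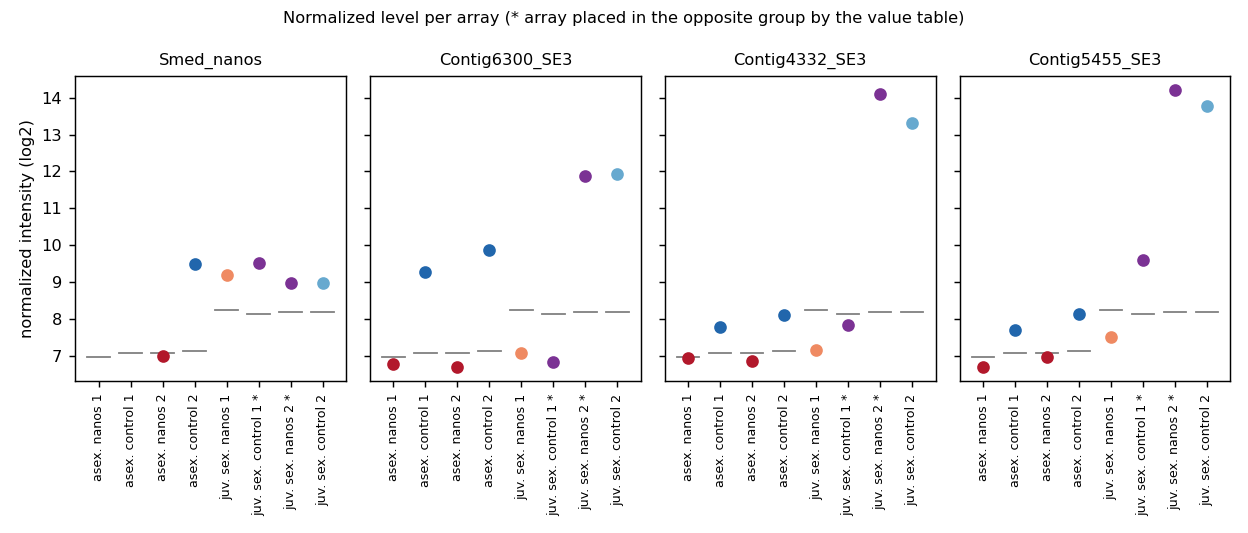
Normalized log2 intensity of nanos and 3 ESTs on each of the 8 arrays (points), with the lowest value among ESTs above background on that array as a grey line; stars mark the 2 arrays whose group differs between the records. Contig6300_SE3 reached 9.28 and 9.86 on the asexual control arrays and 6.76 and 6.69 on the asexual nanos(RNAi) arrays.

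The asexual comparison asks which transcripts depend on nanos, or on the germ cells that nanos(RNAi) removes, in a strain that reproduces asexually. In the fit as planned limma called 0 ESTs with the sample-file grouping and 1, Contig6300_SE3, with the value-table grouping, which does not measure how many changed. Contig6300_SE3 fell by at least 5.88-fold, from 9.28 to 6.76 on the replicate 1 arrays and from 9.86 to 6.69 on the replicate 2 arrays. The files pair this EST with no gene name. Contig6300_SE3 fell in both array sets (log2 −2.52 in set 1 and −3.17 in set 2).

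Over 15789 ESTs, limma called 0 ESTs with the sample-file grouping, where 784 had an unadjusted p under 0.05 and the smallest adjusted p was 0.93. With the value-table grouping, which leaves the asexual arrays as they are and changes only the shared spread, it called 1, Contig6300_SE3 (log2 −2.84, SE 0.191, adjusted p 0.00225), and 895 ESTs had an unadjusted p under 0.05. The count with this grouping was 14 under 75th percentile scaling, 6 with quantile normalization within each strain and 15 in the value table, all lower. The call of Contig6300_SE3 was lost without asexual nanos(RNAi) replicate 1 (log2 −2.88, adjusted p 0.107) or replicate 2 (−2.81, adjusted p 0.128), where the fitted difference hardly moved and 1 array was left in the group. With the asexual array set as a block the counts were 0 (1165 at an unadjusted p under 0.05) and 2, and with the planned block by replicate number in both strains, which for asexual arrays is also the array set, 1 and 1. When the 4 asexual arrays were fitted alone with the array set as a block, a choice made after the data were seen, limma called 32 ESTs lower and 0 higher, 22 of them at least 2-fold lower, among them Contig6300_SE3 (adjusted p 2.4e-05) and Smed_nanos (adjusted p 8.44e-05). For nanos that fit has 1 array per group, so its p rests on the spread of the other ESTs.

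None of the 12 ESTs with gene names passed the threshold in asexual animals in the fit as planned with either grouping. nanos passed in the alternatives given above, and in the fit of the asexual arrays alone nanos and Huntingtin1 (adjusted p 0.0374) did. The lowest by p after nanos were Huntingtin1 (log2 −1.12), Huntingtin2 (−0.79), TIMELESS (−0.42) and robo2 (−0.26), each with 1 array per group. The only higher ones were robo1 (0.16), ZFP (0.13), slit3 (0.09) and VDLA1BCaChannel (0.09).

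The juvenile sexual comparison asks the same of animals of the sexual strain. A large set of ESTs, with the value-table grouping, fell to or near background on the arrays labelled nanos(RNAi). Contig4332_SE3 lay at 14.10 and 13.32 on the arrays that the value table places in control and at 7.16 and 7.83 on those it places in nanos(RNAi), at least 45.7-fold lower. Contig5455_SE3 fell from 14.22 and 13.79 to 7.52 and 9.59, of which only 9.59 lay above background; its log2 difference was −4.41 without nanos(RNAi) replicate 1 and −6.48 without replicate 2 of this grouping. With the sample-file grouping each group holds 1 bright and 1 dim array for these ESTs, and Contig4332_SE3 differed by 0.05 and Contig5455_SE3 by −0.82 (log2; adjusted p 1 each).

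**Figure D2:**
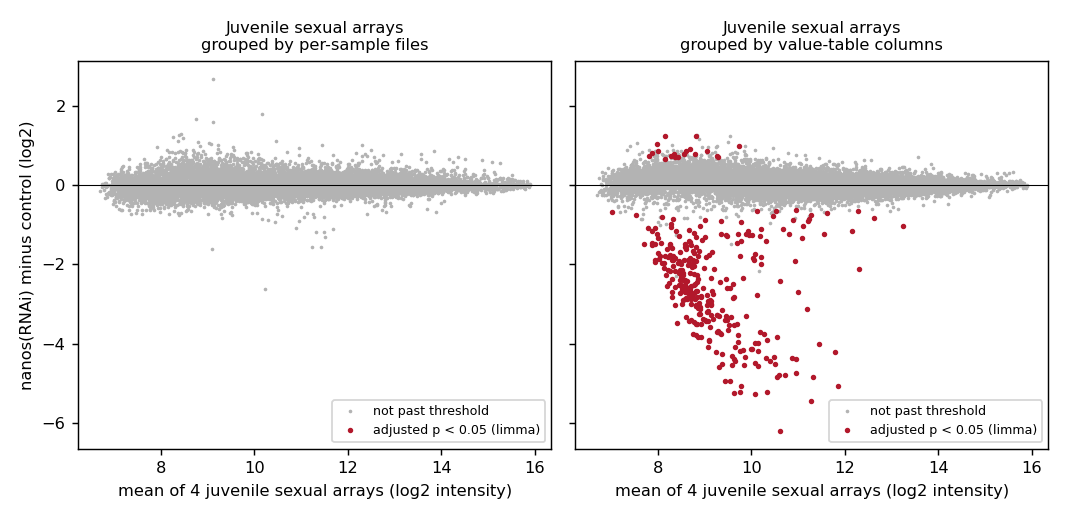
Log2 difference between the juvenile sexual arrays labelled nanos(RNAi) and control against mean log2 intensity, 1 point per EST, with the sample-file grouping (left) and the value-table grouping (right). Red points passed limma's adjusted p threshold: 0 on the left, and 19 higher and 301 lower on the right.

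With the sample-file grouping limma called 0 ESTs (621 at an unadjusted p under 0.05, smallest adjusted p 0.0688). The value-table grouping gave 320 calls, 19 higher and 301 lower; 3 of the higher and 282 of the lower ESTs changed at least 2-fold. None of the higher calls held under 75th percentile scaling (0 higher and 285 lower) or quantile normalization within each strain (0 and 256), while renormalizing the authors' RMA values gave 111 higher and 282 lower. Contig4332_SE3 (log2 −6.21, SE 0.282, adjusted p 6.17e-06) and Contig5455_SE3 (log2 −5.45, SE 0.531, adjusted p 0.00034) had the lowest fitted values of the calls. HB_21_12e_-2 and H_45_3a_-1 had the highest, 1.24 each (adjusted p 0.000652 and 0.02), over controls below background. H_45_3a_-1 was at least 2.07-fold higher. No bound is given for HB_21_12e_-2, since 1 of its nanos(RNAi) arrays lay below background too. With nanos(RNAi) or control arrays below background for these 4 ESTs, the order by fitted value is set by background. The rise of HB_21_12e_-2 did not pass under 75th percentile scaling (0.34, adjusted p 0.903) or quantile normalization within each strain (0.51, adjusted p 0.127). H_45_3a_-1 did not pass there either (0.45, adjusted p 0.718, and 0.60, adjusted p 0.13), nor with the mean of probes, a single on-array copy or the authors' values (adjusted p 0.0508 to 0.459), nor without asexual nanos(RNAi) replicate 1 or 2 (1.24, adjusted p 0.0662 each, where only the shared spread can change) or without juvenile sexual nanos(RNAi) replicate 1 (1.31, adjusted p 0.109) or 2 (1.18, adjusted p 0.169).

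The 301 ESTs that fell with the value-table grouping had a median log2 difference of −2.54 (interquartile range −3.4 to −1.72). Of these ESTs, 192 were at least 4-fold and 42 at least 16-fold lower by fitted value. Since 244 of them lay below background on both arrays in the nanos(RNAi) group, the median with dim ESTs at their bound was 3.54-fold, with 254 at least 2-fold and 128 at least 4-fold lower. These bounds rest on the lowest value above background of each array, so they can overstate the least fold. Only 5 lay below background on both control arrays. Of the 19 higher ESTs, 15 lay below background on both control arrays.

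Juvenile sexual nanos(RNAi) replicate 1 and control replicate 2, the 2 arrays that both records place alike, can be compared without the disputed arrays. Between them 163 ESTs were at least 4-fold lower and 5 at least 4-fold higher on the array labelled nanos(RNAi). The median level of the 163 ESTs was 7.34 on the array labelled nanos(RNAi) replicate 1, 10.5 on control replicate 2, 7.51 on the array filed as control replicate 1 and 11.2 on the array filed as nanos(RNAi) replicate 2. With 1 array per group in this comparison, the 163 ESTs were chosen by size without a test. The arrays compared also carry different replicate numbers. A difference between replicate 1 and replicate 2 animals can therefore not be told apart from an effect of nanos(RNAi) here.

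**Figure D3:**
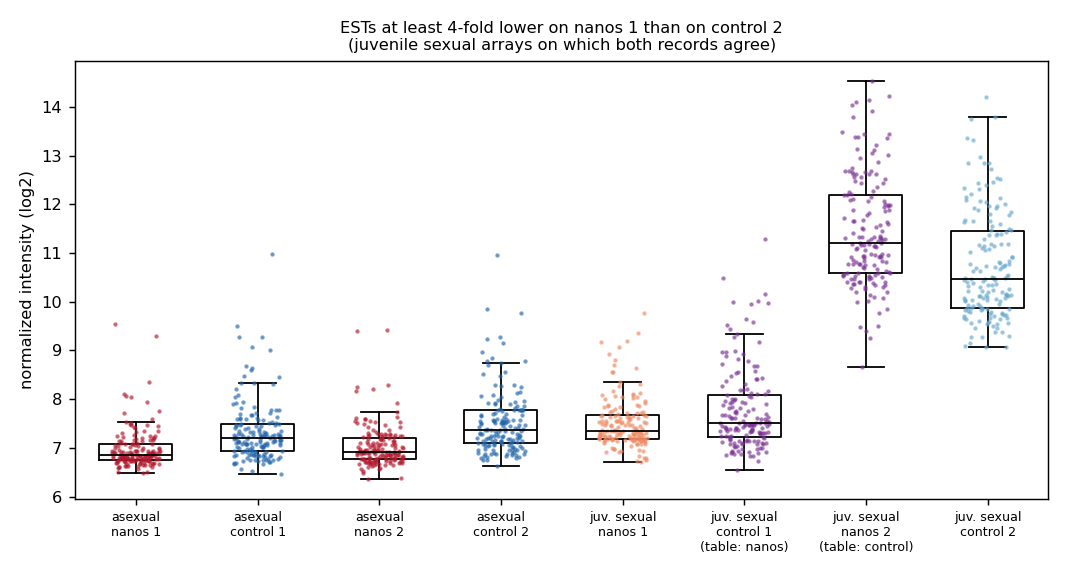
Normalized log2 intensity on each of the 8 arrays of the 163 ESTs at least 4-fold lower on juvenile sexual nanos(RNAi) replicate 1 than on control replicate 2 (points are ESTs; boxes are quartiles with the median, whiskers reach 1.5 interquartile ranges). The array filed as control replicate 1 has a median of 7.51 and the array filed as nanos(RNAi) replicate 2 a median of 11.2.

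None of the 12 ESTs with gene names passed the threshold in juvenile sexual animals with either grouping. Hedgehog lay below background on all 4 juvenile sexual arrays, so its log2 differences involving them are set by background and show no measured change: −0.29 and 0.23 here with the sample-file and value-table grouping, −0.28 and 0.24 for the strain difference in the effect, and −0.24 and −0.50 between the controls. With the sample-file grouping the lowest by p of the others were robo2 (log2 −0.17), VDLA1BCaChannel (−0.13), nanos (−0.16) and TIMELESS (−0.14), and the highest flotillin_-3 (0.11), Huntingtin1 (0.06), slit3 (0.01), Huntingtin2 (0.01) and ZFP (0.01). Grouped by the value table, TIMELESS (−0.41), flotillin_-3 (−0.02), slit3 (−0.01) and robo2 (−0.01) were lower, and nanos (0.36), Huntingtin1 (0.21), ZFP (0.21) and VDLA1BCaChannel (0.16) led the higher ones.

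Whether the same ESTs fell in both strains was asked next. The ESTs that fell in juvenile sexual animals with the value-table grouping also tended to be lower in asexual nanos(RNAi) animals. The fitted falls were smaller there, but many of these ESTs were too dim in asexual control animals for a larger fall to be measured. Of the 301 ESTs, 262 were lower in asexual nanos(RNAi), 227 of them in both array sets, with a median log2 difference of −0.21 (−0.17 in set 1 and −0.26 in set 2). In 10000 random lists matched on mean intensity the median was 0.02 and the lowest −0.01, and 0 lists were as low. The random lists hold unrelated ESTs, while the 301 were chosen for moving together, so the lists can understate the spread of such a median. They also resample ESTs and not animals, with 2 asexual arrays per group. Among the 301, 53 had an unadjusted p under 0.05 in the asexual comparison and 24 passed adjusted over the list alone; these 2 counts use a spread shared with the juvenile sexual arrays on which the list was chosen, so they are not independent of that choice. The median levels of these ESTs were 7.34 in asexual control and 6.97 in asexual nanos(RNAi), and 111 of them lay below background on both asexual control arrays.

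**Figure D4:**
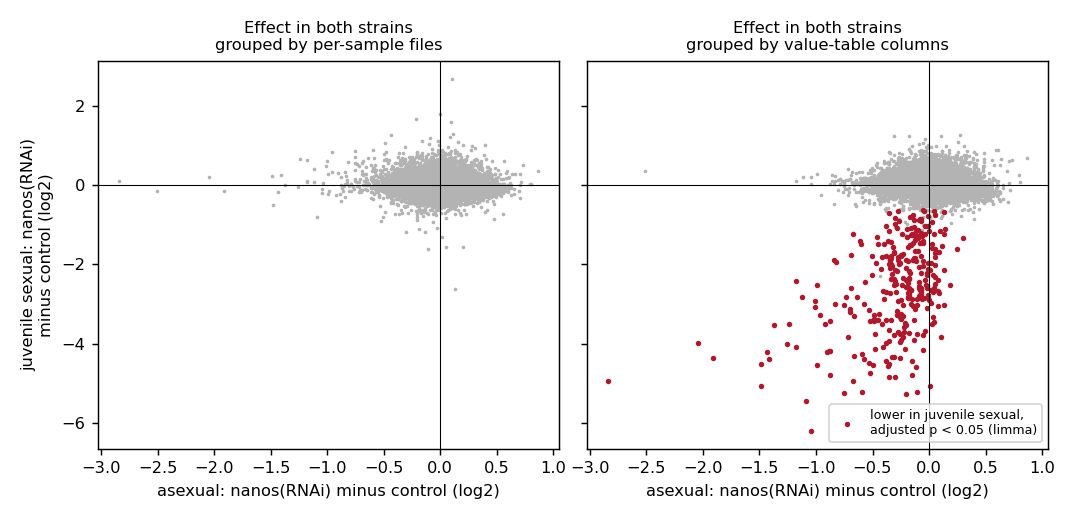
Log2 difference nanos(RNAi) minus control in juvenile sexual animals against that in asexual animals, 1 point per EST, with the sample-file grouping (left) and the value-table grouping (right). Red points, in the right panel only, are the 301 ESTs called lower in juvenile sexual animals by limma with the value-table grouping, and 262 of them lie left of 0. With the sample-file grouping limma called 0.

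By calls, 0 ESTs were lower in both strains with the sample-file grouping and 1, Contig6300_SE3, with the value-table grouping, where 0.0191 were expected of unrelated lists (two-sided Fisher's exact p 0.0191). The latter count was 13 under 75th percentile scaling, 5 with quantile normalization within each strain and 13 in the value table. Among the 100 lowest ESTs by rank in each strain, 1 was shared with the sample-file grouping (0.633 expected, exact p 0.471) and 21 with the value-table grouping (exact p 1.01e-26). Among the 500 lowest, 19 were shared (15.8 expected, exact p 0.434) and 56 (exact p 1.26e-16). The effects correlated across all ESTs at r = −0.02 and 0.18. These exact tests treat ESTs as independent, which they are not.

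The mean effect over both strains gave 0 calls by limma with the sample-file grouping (664 at an unadjusted p under 0.05) and 264 with the value-table grouping, 2 higher and 262 lower. The split was 0 higher and 262 lower under 75th percentile scaling, 0 and 216 with quantile normalization within each strain, and 31 and 241 from the authors' RMA values renormalized. Contig6300_SE3 (log2 −3.90, adjusted p 7.09e-06) and Contig4332_SE3 (−3.63, adjusted p 2.8e-05) had the lowest fitted values; both lay below background on all nanos(RNAi) arrays in this grouping, so these sizes and their order are set by background. H_29_4a_T3_2 rose by 0.51 (adjusted p 0.0294), a call lost under 75th percentile scaling (0.31, adjusted p 0.781), quantile normalization within each strain (0.37, adjusted p 0.143), from the authors' RMA values renormalized (0.64, adjusted p 0.188) and in the value table (0.57, adjusted p 0.535). Of the 264 ESTs, 262 were also called in juvenile sexual animals alone. With the asexual array set as a block the counts were 0 (962 at an unadjusted p under 0.05) and 250. Among ESTs with gene names, nanos (log2 −1.34), Huntingtin1 (−0.53), Huntingtin2 (−0.39), robo2 (−0.22) and TIMELESS (−0.28) were the lowest by p with the sample-file grouping, none past the threshold, and robo1 (0.06), slit3 (0.05) and ZFP (0.07) the only higher ones. Grouped by the value table, nanos (−1.07, adjusted p 0.00926) passed, a value that rests on 1 asexual array per group and on juvenile sexual signal near background, followed without passing by Huntingtin1 (−0.45), TIMELESS (−0.41), Huntingtin2 (−0.32) and robo2 (−0.14), and ZFP (0.17), VDLA1BCaChannel (0.12), robo1 (0.11) and slit3 (0.04) were higher.

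Whether the effect of nanos(RNAi) differed between the strains was tested directly. By fitted values with the value-table grouping, most differing ESTs fell more in juvenile sexual than in asexual animals, but many were too dim in asexual animals for a fall to be measured. Contig4332_SE3 changed by −6.21 in juvenile sexual and −1.04 in asexual animals, a fitted log2 difference of −5.17 (SE 0.398, adjusted p 0.000525); it lay below background on all nanos(RNAi) arrays of both strains in this grouping, so the size of the difference is set by background. PL06018B2A09_SE3 had a fitted difference of −5.11 (adjusted p 0.000625), but it lay below background on all 4 asexual arrays, so that whether its fall differed between the strains cannot be known. Of the 208 ESTs with a negative difference, 181 were lower in both strains, and 97 lay below background on both asexual control arrays, where a fall cannot be measured.

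limma called 0 ESTs for this difference with the sample-file grouping (629 at an unadjusted p under 0.05) and 213 with the value-table grouping, 5 positive and 208 negative. The positive ones included nanos (2.87, adjusted p 0.00344), whose size is set by background, since its asexual nanos(RNAi) array lay below it and its juvenile sexual arrays near it, with 1 asexual array per group, HB_21_12e_-2 (1.42, adjusted p 0.00572), whose size is set by background since both juvenile sexual control arrays and 1 nanos(RNAi) array lay below it, and Contig5654_SE3 (1.24, adjusted p 0.0351). HB_21_12e_-2 lost its call under 75th percentile scaling (0.51, adjusted p 0.653), with quantile normalization within each strain (0.70, adjusted p 0.242) and in the value table (1.28, adjusted p 0.11). Contig5654_SE3 lost its call in the same 3 settings (1.30, 1.29 and 1.26, adjusted p 0.156, 0.0955 and 0.396) and from the authors' RMA values renormalized (1.22, adjusted p 0.125), with fitted values of similar size. The count fell to 113 without asexual nanos(RNAi) replicate 1, 102 without asexual nanos(RNAi) replicate 2 and 141 without asexual control replicate 1, to 44 under 75th percentile scaling, to 70 with quantile normalization within each strain and to 29 in the authors' value table. With the asexual array set as a block it was 0 (964 at an unadjusted p under 0.05) and 189. Among other ESTs with gene names, Huntingtin1 (1.33, adjusted p 0.0725), Huntingtin2 (0.93) and robo2 (0.26) were the highest with the value-table grouping and slit3 (−0.10) and robo1 (−0.10) the only negative ones. With the sample-file grouping nanos (2.35), Huntingtin1 (1.18), Huntingtin2 (0.80), flotillin_-3 (0.25) and TIMELESS (0.28) were the highest, and robo1 (−0.20), VDLA1BCaChannel (−0.21), ZFP (−0.12) and slit3 (−0.08) the lowest by p, none past the threshold.

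The control arrays of the strains differed over most ESTs. Contig4565_SE3 was at least 103-fold higher in juvenile sexual than in asexual control animals with the sample-file grouping and at least 89.3-fold with the value-table grouping, and Contig5668_SE3 at least 124-fold and 142-fold. Contig7119_WUSTL was at least 64.9-fold and 64.2-fold lower, and NB_26_5d at least 62.5-fold and 73.1-fold. Of the ESTs with gene names, Huntingtin2 (log2 2.65 and 2.58), TIMELESS (2.33 and 2.46), ZFP (1.84 and 1.74), Huntingtin1 (1.73 and 1.66), VDLA1BCaChannel (1.69 and 1.55) and robo2 (0.74 and 0.66) were higher in juvenile sexual control animals, each against 1 asexual control array. flotillin_-3 was lower by these values (−0.72 and −0.65), and turned to higher under 75th percentile scaling (0.28, adjusted p 0.0846, and 0.38, adjusted p 0.0343). nanos (−0.25 and −0.51) and netrin2 (−0.14 and −0.17) did not pass.

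limma called 9475 ESTs with the sample-file grouping, 4437 higher and 5038 lower, and 10104 with the value-table grouping, 4708 higher and 5396 lower, which is 60% and 64% of those tested. At least 2-fold, 1842 were higher and 2393 lower with the sample-file grouping, and 2017 and 2516 with the value-table grouping. Both groupings called 9026 ESTs in the same direction, 4153 higher and 4873 lower. Under 75th percentile scaling 6562 ESTs were higher and 4290 lower with the sample-file grouping and 6753 and 4337 with the value-table grouping, and the median of all ESTs moved from −0.02 and −0.05 to 0.22 and 0.22. With the array set as a random block the counts were 8993 and 9576. Strain, culture salts, temperature and array set change together in this comparison, so their shares cannot be told apart.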

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

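The tests of exchanged arrays, of the nanos signal and of the list shared between strains were chosen only after the result was seen.

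With the value-table grouping, limma's test of the difference in the nanos(RNAi) effect between the strains called 213 ESTs. With the sample-file grouping it called 0 (629 at an unadjusted p under 0.05). Of the 208 ESTs with a negative difference, 97 lay below background on both asexual control arrays, where a fall cannot be measured. The count of 213 fell to 44 under 75th percentile scaling, 70 with quantile normalization within each strain and 29 in the value table. Among ESTs above background on all arrays it was 2, but that filter also leaves out ESTs that fell to background. Contig4332_SE3 had a fitted log2 difference of −5.17, with its nanos(RNAi) values below background in both strains. PL06018B2A09_SE3 had one of −5.11, but lay below background on all 4 asexual arrays, where no fall could be measured. HB_21_12e_-2 had one of 1.42, with both juvenile sexual control arrays below background, so its size is set by background. Contig5654_SE3 had one of 1.24, but in the same fit neither its change in asexual animals (−1.04, limma adjusted p 0.209) nor that in juvenile sexual animals (0.20, adjusted p 0.903) passed. Its fall in asexual animals did pass when the asexual arrays were fitted alone with the array set as a block (limma adjusted p 0.0194). Its call for the difference was also lost under other scalings, as given above. Smed_nanos had one of 2.87, whose size is set by background, with 1 asexual array per group and no fall measurable in juvenile sexual animals.

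The count of 213 changes with the place of 2 juvenile sexual arrays. Over the 32 ESTs called lower in the asexual arrays alone, the array filed as control replicate 1 minus the array filed as nanos(RNAi) replicate 2 had a median log2 of −3.96 (interquartile range −4.4 to −2.46, 26 of 32 below 0). Only if animals responded as labelled and the replicates did not differ does this argue against exchanged value-table columns as the only fault. The same −3.96 is consistent with scans attached to each other's sample. Scans rightly attached to animals that differed from their labels cannot be told apart from this, since the array filed as control replicate 1 lay below control replicate 2 too (median −3.32) and no other record identifies the arrays. A difference between replicates 1 and 2 as filed cannot be told apart either. Over the same ESTs, control minus nanos(RNAi) had a median of 0.164 between the arrays filed as replicate 1. Between those filed as replicate 2, nanos(RNAi) minus control had a median of 0.48. Chance sharing of unrelated lists is argued against by 25 of the 32 ESTs lying among the 301 lower in juvenile sexual animals with the value-table grouping, where 0.61 were expected (two-sided Fisher's exact p 1.11e-37). That test treats ESTs as independent, which they are not. The overlap shows ESTs that vary together, and does not by itself show a response to nanos(RNAi) in juvenile sexual animals.

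On the 4 juvenile sexual arrays, the nanos EST in nanos(RNAi) animals did not pass the threshold with either grouping. Its log2 difference from control was −0.16 with the sample-file grouping and 0.36 with the value-table grouping. Its raw probes reached at most 1.18 times the background level on those 4 arrays, so a signal close to background is a candidate explanation. Whether nanos RNA was reduced in those animals cannot be told apart from this, since the difference between the arrays that both records place alike was 0.20 at that signal. A difference between the strains in the knockdown of nanos stays open and untested.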

How the results depend on the processing

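The value-table grouping, the fits on arrays that both records place alike and the fits with the asexual array set as a block were chosen only after the result was seen.

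With the sample-file grouping, the effect of nanos(RNAi) gave 0 calls in each strain, for the mean and for the difference under every setting not named here. In juvenile sexual animals limma called 1 EST without background correction, 1 with quantile normalization within each strain, 2 with the mean of probes and 1 with trend and robust moderation. In asexual animals it called 1 under 75th percentile scaling, 1 from the 4 asexual arrays alone, 1 with the replicate block and 32 from the 4 asexual arrays alone with the array set as a block, a fit that holds for both groupings. The value table carries its own grouping, and from it limma called 15 ESTs in asexual animals, 245 in juvenile sexual animals, 208 for the mean, 29 for the difference and 13 lower in both strains. The value-table grouping of the values made here gave 1, 320, 264, 213 and 1 in the same order, and the arrays that both records place alike gave 1, 259, 238, 179 and 1. That last fit has 1 juvenile sexual array per group and takes its spread from the asexual arrays only, so its counts for juvenile sexual animals, the mean and the difference are not those of a replicated comparison. By rank, 1 EST was shared among the 100 lowest of each strain and 19 among the 500 lowest. The strain comparison of controls kept 4235 calls at 2-fold or more, where the fold limit itself removes calls.

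The nanos difference in juvenile sexual animals (log2 −0.16) turned positive with the second on-array copy (0.11), the authors' RMA values (0.039), these renormalized (0.044), the value table (0.45), the value-table grouping (0.36) and the arrays that both records place alike (0.20). Leaving out each array gave −0.42 to 0.10, positive only without juvenile sexual control replicate 1. Its probes lay at 0.927 to 1.18 times background there; beyond that the cause was not tested.

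Under the value-table grouping, the asexual count moved from 1 to 14 under 75th percentile scaling, 6 with quantile normalization within each strain, 2 with the second copy, 15 in the value table, 0 with the filter on all 8 arrays (928 at an unadjusted p under 0.05), 2 with trend and robust moderation and 2 with the asexual array set as a block. The juvenile sexual count moved from 320 to 493 with no filter (16797 ESTs tested) and 15 with the filter on all 8 arrays (12605 tested), which leaves 31 of the 301 lower ESTs; the mean count moved to 8 there. The count for the difference was 44 under 75th percentile scaling, 70 with quantile normalization within each strain, 29 in the value table and 2 with the filter on all 8 arrays. Calls lower in both strains were 13, 5, 2, 13, 0 and 2 under 75th percentile scaling, quantile normalization within each strain, the second copy, the value table, the filter on all 8 arrays and trend with robust moderation, and by rank 21 of the 100 and 56 of the 500 lowest. The strain comparison of controls kept 4533 at 2-fold or more. Where the filter is not the reason, the cause was not tested.

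Leaving out each array in turn gave, with the sample-file grouping, 0 to 0 calls for each effect of nanos(RNAi) and 7511 to 9211 for the strain comparison. The value-table grouping gave 0 to 2 in asexual animals (0 without either nanos(RNAi) array), 255 to 340 in juvenile sexual animals, 189 to 313 for the mean, 102 to 285 for the difference, 8679 to 9951 for the strain comparison and 0 to 2 lower in both strains. Where this left 1 array in a group, limma assumes that it varies like the others. Of the 301 lower ESTs, all kept their sign in each of these fits with the value-table grouping where they were tested; 279 remained called under 75th percentile scaling, 251 with quantile normalization within each strain and 240 in the value table.

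The replicate numbers only share a number in the juvenile sexual groups, and arrays of the same number deviated together at r = 0.744 with the sample-file grouping and 0.128 with the value-table grouping (0.408 in the asexual groups, where the number is also the array set). With the replicate number as a block, the counts with the sample-file grouping were 1 in asexual and 0 in juvenile sexual animals (1125 at an unadjusted p under 0.05), and with the value-table grouping 1 and 331, with 261 for the mean and 212 for the difference.

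Subtraction of mismatch probes was not run since the column is 0, and camera with an estimated correlation and fry were not run since no gene list had enough members. The strain comparison was not run with quantile normalization within each strain, nor on the authors' RMA values without a further quantile step or the value table, whose column medians differ between the array sets. Signal over background limits the juvenile sexual values: 244 of the 301 lower ESTs lay below background on both arrays of the nanos(RNAi) group, so their folds are bounds.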

Other observations

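The tests of labelling along the transcript and of dimness were chosen only after the result was seen; the tests of array sets and of other divisions of the arrays were planned.

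Over 60% of ESTs differed between the strains' control arrays with either grouping. Dim juvenile sexual arrays as the whole cause are argued against, since among the 12605 ESTs above background on all 8 arrays 63.1% differed with the sample-file grouping and 63.8% with the value-table grouping. Labelling that differed along the transcript is a candidate explanation for part of it: within ESTs, the difference between the strains changed by a median of −0.136 log2 per 100 bases of probe position (71.4% of ESTs negative), against −0.0126 between the asexual array sets and 0.00431 and −0.00016 within sets 2 and 3. Between the asexual array sets 26 of 15778 ESTs differed (SD 0.25 log2, against 1.04 and 1.11 between the strains), but set 3 holds all the juvenile sexual arrays, so strain and array set cannot be told apart. A biological difference between the strains stays open and untested.

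For the mean effect of nanos(RNAi), 34 of the 35 divisions of the 8 arrays into 4 and 4 could be fitted. With the sample-file grouping the real division called 0 ESTs and the highest of the others 311; every division reaches 0, so the 34 of 34 that did says nothing about chance. With the value-table grouping the real division called 264 ESTs. Of the 34 divisions 2 gave as many, the real division itself and the one with 311, so chance is not excluded. The division with 311 follows the asexual array sets together with the value-table grouping of the juvenile sexual arrays; with the array set as a block the real division called 250. The 6 divisions that group the juvenile sexual arrays as the value table does called 213 to 311 ESTs and the other 28 called 0 to 1, which points to a structure of the juvenile sexual arrays.

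The 301 ESTs lower in juvenile sexual animals with the value-table grouping were unevenly spread over the kinds of identifier. Identifiers that start with PL and end with SE3 made up 36.5% of them and 22.3% of the ESTs tested (110 of 301, two-sided Fisher's exact p 1.52e-08 over ESTs). Contigs ending with SE3 made up 58.8% against 45.3% (exact p 2.56e-06), and contigs ending with WUSTL 2.33% against 11.9% (exact p 1.45e-09).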
